A study of Mus musculus with 125 samples.

How the data were processed

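The series measured RNA in single mouse embryos at the 2-cell stage. Per the labels' protocols, zygotes were selected 10 h after fertilization, the second polar body was removed and embryos were collected at 34 h. Libraries were made with a SMART-Seq v4 kit for low input and a Nextera XT kit. HISAT2 2.0.5, featureCounts 2.0.0 and the genome build GRCm38 are named per the submitters' processing notes. The deposited values are estimated counts per gene, not scaled to depth, in which 28.4% of the values were not whole numbers. The annotation release, the use of strand and the rule for shared reads are not given in the sources used here. The table held 43421 genes, of which 1081 had no count in any library, and 125 libraries. Of its gene identifiers 43266 matched a table of symbols, and 32346 matched a RefSeq table of GRCm38.p6, the source of coordinates and gene types.

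Groups follow the labels for strain, pronuclei and the submitters' in silico call. The labels do not say which strain of a cross was the mother. The 4 libraries left out of all comparisons were 1 labelled dead and 3 labelled of low quality. No pair of libraries of 1 group looked like a library deposited in 2 copies, since the lowest chi-square per gene was 16.9. The submitters' set of listings differs between accessions and is not called a batch by the labels.

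The estimated counts were rounded to whole numbers first. Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test with TMM factors and filterByExpr by group), with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons of 1PN, 1PN called parthenogenetic and 2PN embryos over both crosses came from an additive fit of 6 groups with cross as a term. The comparisons within a cross, between crosses, with parthenotes and between reciprocal 2PN embryos came from a fit of the means of all 7 groups. Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists of 1 comparison, for lists with at least 5 tested members. No list that camera called passed with an estimated correlation, which gives a larger p where members move together. This was not tried for lists tested with embryos left out. The 23 lists cover 2-cell stage transcripts, ribosome biogenesis, oocyte-derived transcripts, Y-linked genes, imprinted genes of either parent, nuclear import and envelope, chromatin and DNA methylation, DNA replication, mitosis, p53 targets, stress, apoptosis, ribosomal proteins, proteasome, splicing, the respiratory chain, mitochondrially encoded genes, glycolysis, and early lineages. They also cover markers of cumulus and granulosa cells, of sperm and testis, and of blood, immune and other cells.

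Groups, tests, alternatives, lists and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after seeing the data. For each comparison the rule names the 10 genes with the largest and the 10 with the most negative log2 fold change among those past the threshold. These needed a mean of at least 10 CPM in the higher group and at least 1 count in at least 0.5 of its embryos. Gene models without a proper symbol and pseudogenes were left out. Up to 4 members with the smallest p of each list discussed, Xist and Y-linked genes were added. Only some of these genes are named in the text, and results on some items are not reported here. A fold change against a group with 0 counts was computed against a floor of 3 counts over the group. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Exact intervals of shares treat each embryo as a unit, and approximate intervals of fold changes use the SE of the fit.

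Library measures (total counts, genes with counts, shares of mitochondrial, Y-linked and of the 50 most counted genes, and summed CPM of 3 marker lists) were compared in 9 pairs of groups, which makes 72 tests in 1 family. The spread of a group was the mean of 1 minus Spearman's rho between each embryo and the mean log2(CPM + 1) of the others, over 23971 genes, in 9 tests. Both used 2-sided permutation tests of the difference in means with Benjamini-Hochberg adjustment, exact where there were at most 1000000 arrangements and otherwise with 100000 resamples. For 8 embryos against 43 or 31 the plan called for exact tests, and resamples were used instead. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these and for the figures. The principal components used 12299 genes.

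The test was checked on simulated data drawn once per comparison with the means, within-group spread and library sizes of the real embryos, with 200 genes changed. For 1PN against 2PN, over 21538 genes, edgeR called 200 genes, of which 93 were unchanged (46.5%). It recovered 39% of genes changed 2-fold and 68% of those changed 4-fold. Among genes with a mean of at least 10 CPM, 18 of 84 calls were false, and 68.1% and 94.4% were recovered. Without restriction the false calls were 97 of 190 for 1PN embryos called parthenogenetic against 2PN, 158 of 288 for parthenotes against 2PN, 82 of 148 for 1PN embryos called parthenogenetic against parthenotes and 62 of 166 for reciprocal 2PN embryos. With 3 1PN embryos of JF1/Ms x C57BL/6 it recovered 2% of genes changed 2-fold and 37% of those changed 4-fold. In these simulations the adjusted p of edgeR was too small, mostly for genes of low count. For comparison, 9 of 92 limma voom calls and 16 of 100 calls with a stricter filter were false in the same simulation of 1PN against 2PN. Limma voom was not better throughout, with 157 of 247 calls false for reciprocal 2PN embryos and 16 of 49 for 1PN against 2PN in JF1/Ms x C57BL/6, where edgeR had 19 of 58.

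The alternatives tried were other scalings (RLE factors, library totals alone, upper-quartile factors), no filter and a stricter filter on low counts, DESeq2 1.42.0, limma voom with array weights, and an older form of the edgeR quasi-likelihood test. Others were fits of only the groups compared, the listing set as a term, counts thinned to 1531882 per library (which left out 6 libraries) and embryo numbers as a block. The last were groups as scored under the microscope, low-quality and dead libraries put back, other list tests, and embryos left out in turn. Each cross alone means the within-cross contrast of the fit of all 7 groups, not a separate fit. It was added after seeing the data, as were protein-coding genes only. So was, in some comparisons, each C57BL/6 x JF1/Ms embryo scored 1PN left out in turn. Fits with embryos 1 and 2 of the JF1/Ms x C57BL/6 1PN group called parthenogenetic left out together were added then too. So were gene lists without embryo 9 of the C57BL/6 x JF1/Ms 1PN group or without those 2 embryos.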

Results

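Single mouse embryos were profiled by RNA sequencing at the 2-cell stage to compare embryos from zygotes with 1 pronucleus (1PN) with embryos from zygotes with 2 separate pronuclei (2PN). Hybrids of the inbred strains C57BL/6 and JF1/Ms were made in both directions. Some embryos scored as 1PN under the microscope were called parthenogenetic in silico by the submitters, meaning that they lacked a paternal genome, and C57BL/6 parthenotes served as a control. The cross C57BL/6 x JF1/Ms gave 43 2PN embryos, 11 1PN embryos and 8 1PN embryos called parthenogenetic. The cross JF1/Ms x C57BL/6 gave 21, 3 and 4, and there were 31 parthenotes. Below, 1PN without further words means the embryos not called parthenogenetic. The 121 libraries compared held from 533116 to 4887190 gene counts, with a median of 3392243. In C57BL/6 x JF1/Ms the mean depth was 3817800 ± 648430 (SD, n = 43) for 2PN embryos, 3426200 ± 709510 (SD, n = 11) for 1PN embryos and 3423900 ± 502310 (SD, n = 8) for 1PN embryos called parthenogenetic. In JF1/Ms x C57BL/6 it was 2333100 ± 945530 (SD, n = 21), 3043100 ± 137590 (SD, n = 3) and 2455900 ± 1393300 (SD, n = 4) in the same order, and for parthenotes it was 3151500 ± 493580 (SD, n = 31). No label used here says which embryos share parents, so p-values measure only the spread between these embryos.

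**Figure D1:**
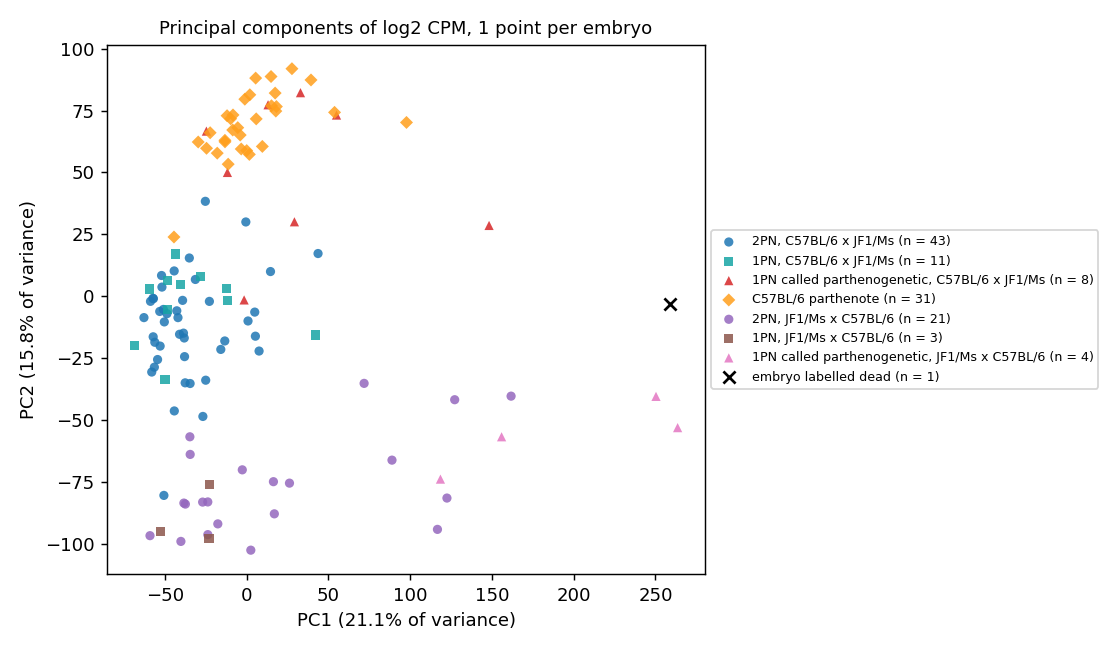
First principal component of log2 CPM (x axis, 21.1% of variance) against the second (y axis, 15.8%), with 1 point per embryo and groups shown by colour and shape. Embryos 1 and 2 of the 1PN group called parthenogenetic of JF1/Ms x C57BL/6, at 263.56 and 250.34 on the x axis, lay near the embryo labelled dead, at 258.95. Embryos 7 and 3 of that group lay at 155.93 and 118.54, and embryo 10 of the 1PN group called parthenogenetic of C57BL/6 x JF1/Ms at 148.27. Some 2PN embryos of JF1/Ms x C57BL/6 lay as far out, with embryo 8 at 161.73, embryo 21 at 127.25, embryo 6 at 122.51 and embryo 3 at 116.71.

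Y-linked genes, which only sperm can bring, and Xist, the non-coding RNA that coats an inactive X chromosome, were used to check the labels. At least 10 summed Y-linked counts were found in 41 of 78 biparental embryos (52.6%, exact 95% interval 40.9% to 64.0%) and in 7 of 43 parthenogenetic embryos (16.3%, 6.81% to 30.7%; Fisher's exact test, 2-sided, p = 8.95e-05). The 7 were all C57BL/6 parthenotes, with at most 23 counts, against up to 1259 in 2PN embryos. At least 50 counts were found in 40 of 78 and 0 of 43 embryos, which allows a share of up to 8.22% (exact 95% interval, p = 1.72e-10), and every embryo had at least 1. At least 10 Xist counts were found in 22 of 78 biparental embryos (28.2%) and in 28 of 43 parthenogenetic embryos (65.1%; Fisher's exact test, 2-sided, p = 0.000107). These were 22 of 31 parthenotes and 6 of 8 1PN embryos called parthenogenetic of C57BL/6 x JF1/Ms, and 0 of 4 of the reciprocal cross. Biparental embryos include males, which have no paternal X chromosome, so the difference in shares also carries the sex of the embryos. Parthenogenetic embryos have no paternal X chromosome either, and the plan expected them to lack paternally expressed Xist. The 28 of 43 with at least 10 Xist counts went against that expectation, so Xist did not bear out the labels, and why was not tested. Their higher share is no evidence on the labels, because males lower the biparental share. Xist overlaps its antisense partner Tsix, and since no use of strand in the counting is stated their reads cannot be told apart. How the in silico call was made is not given in the sources used here. If it used these libraries, the Y-linked counts are not independent of it.

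**Figure D2:**
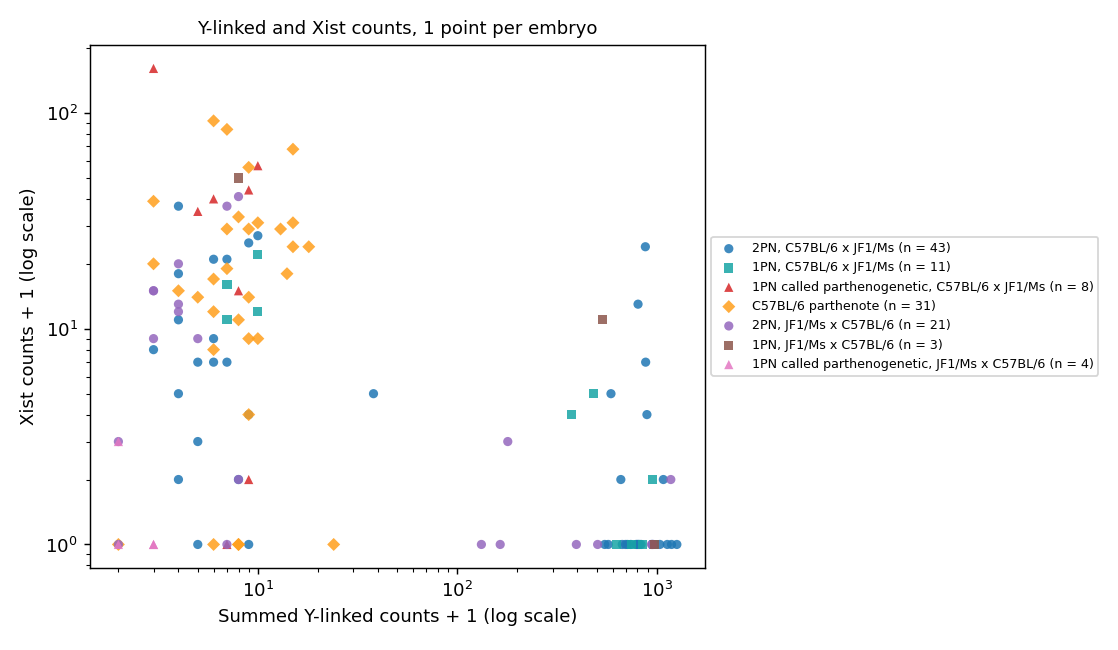
Summed Y-linked counts plus 1 (x axis, log scale) against Xist counts plus 1 (y axis, log scale), with 1 point per embryo and groups shown by colour and shape. The 43 parthenogenetic embryos reached at most 23 Y-linked counts, and 2PN embryos of C57BL/6 x JF1/Ms reached 1259.

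The series asks how embryos develop when the parental genomes lie in separate pronuclei, and the first comparison set 1PN against 2PN embryos. Few genes separated them. Irx2, an Iroquois homeobox transcription factor on chromosome 13 at 72624430 to 72634196 (GRCm38), was higher in 1PN embryos by a log2 fold change of 2.77 ± 0.49 (SE; edgeR quasi-likelihood test, adjusted p = 0.000401, above the 2PN median of their cross in 12 of 14 embryos). Its mean in C57BL/6 x JF1/Ms was 14.4 CPM ± 16.9 (SD, n = 11) in 1PN embryos and 2.16 CPM ± 3.75 (SD, n = 43) in 2PN embryos. Hip1, an endocytic adaptor, stood at 2.01 ± 0.46 (adjusted p = 0.0337, 8 of 14), and Usp17la and Pramef6, of multicopy families with 2-cell stage transcripts, at 2.44 ± 0.57 (adjusted p = 0.0419, 7 of 14) and 1.94 ± 0.45 (adjusted p = 0.0416, 9 of 14). Members of such families share reads, so which copy was counted is uncertain. Of the 22785 genes tested 23 were higher and 0 lower, and 14 of the 23 were pseudogenes, 11 of them Obox4 pseudogenes.

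These calls rested on few embryos. Without embryo 9 of the C57BL/6 x JF1/Ms 1PN group only Irx2 passed, and Usp17la, Pramef6 and Hip1 stood at -0.37, -0.28 and -0.33. DESeq2 called 8 genes and limma voom 1, neither of them Irx2. An unadjusted edgeR p under 0.05 was reached by 1120 of 22785 genes. This is a smaller share than the 9.73% of unchanged genes that reached it in simulated data. The count therefore does not point to further changed genes. Of the lists of related genes, 2-cell stage transcripts had 2 of 44 higher and 0 lower, or 6 and 0 adjusted over the list alone (camera, adjusted p = 0.927). The oocyte-derived list had 0 members past the threshold and a median of -0.26 (camera, adjusted p = 0.00486, and adjusted p = 0.992 with an estimated correlation). The Y-linked list, which follows the sexes that fell into each group, also had 0 members past it (camera, adjusted p = 0.00682, and adjusted p = 0.992 with an estimated correlation). The other lists had 0 members past the threshold, also when adjusted over the list alone, and none passed camera. Without embryo 9 proteasome genes, with a median of 0.15 (camera, adjusted p = 0.00170), and mitochondrially encoded genes, with -0.18 (camera, adjusted p = 0.0293), passed as well. An estimated correlation was not tried without embryo 9. Among the 9092 genes with a mean of at least 10 CPM, the approximate 95% interval lay within 2-fold in either direction for 7869 (86.6%).

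Within C57BL/6 x JF1/Ms, Usp17la stood at 2.92 ± 0.54 (adjusted p = 0.000441, 7 of 11), Zscan4b, of a family that marks the first strong transcription of the embryonic genome, at 2.39 ± 0.51 (adjusted p = 0.00520, 9 of 11) and Pramef6 at 2.26 ± 0.45 (adjusted p = 0.00154, 8 of 11). The list of 2-cell stage transcripts did not pass, with 5 of 44 higher and 0 lower, or 11 and 0 adjusted over the list alone (camera, adjusted p = 0.910). Without embryo 9 Zscan4b and Pramef6 stood at -0.30 and -0.25. Irx2 stood at 2.62 ± 0.50 (adjusted p = 0.000635, 10 of 11). In all 48 of 24380 genes were higher and 0 lower, 26 of them pseudogenes, and without embryo 9 the count was 0. Limma voom called 0 genes and DESeq2 24. An unadjusted edgeR p under 0.05 was reached by 1094 of 24380 genes, again a smaller share than in simulated unchanged genes (9.43%). In JF1/Ms x C57BL/6, with 3 1PN embryos, Irx2 stood at 3.47 ± 1.64 (adjusted p = 0.51), Usp17la at -2.89 ± 1.36 (adjusted p = 0.51), Zscan4b at -2.49 ± 1.46 (adjusted p = 0.593), Hip1 at -0.62 ± 1.04 (adjusted p = 0.859) and Pramef6 at -0.41 ± 0.98 (adjusted p = 0.907). None of the 5 passed edgeR there, and all but Irx2 had the opposite sign to C57BL/6 x JF1/Ms. There 2 gene models passed, both higher, 1700016D06Rik and Gm34885, which were named after their values were seen. There 2232 of 24380 genes had an unadjusted p under 0.05, a larger share than in simulated unchanged genes (5.86%). Other splits of the embryos of this cross into groups of the same sizes gave up to 2515 genes past the threshold. In JF1/Ms x C57BL/6 DESeq2 called 663 and limma voom 95. The test of whether the 1PN effect differed between crosses gave 0 genes with edgeR, 484 with DESeq2 and 47 with limma voom. At an unadjusted edgeR p under 0.05 it gave 2169 of 24380, with no simulated share to set this against.

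Embryos scored as 1PN but called parthenogenetic had fewer transcripts for making ribosomes than 2PN embryos. Ribosome biogenesis genes had 0 of 51 higher and 48 lower, or 0 and 50 adjusted over the list alone. The list median was -1.18 (camera, adjusted p = 2.48e-24, and adjusted p = 0.232 with an estimated correlation). Tsr1, a 40S maturation factor on chromosome 11 at 74898080 to 74909340 (GRCm38), fell by 3.30 ± 0.30 (adjusted p = 1.6e-14, 12 of 12), Wdr12, a 60S factor, by 1.84 ± 0.30 (adjusted p = 1.03e-06, 12 of 12) and Nolc1, a nucleolar phosphoprotein, by 1.34 ± 0.22 (adjusted p = 6.76e-07, 11 of 12). Here and below, the log2 fold change is given with its SE, the adjusted p is from edgeR, and the last numbers give the embryos beyond the median of the other group in their own cross. Ribosomal protein genes, whose processed copies make single members uncertain, had 0 of 74 higher and 70 lower, or 0 and 71 adjusted over the list alone. As a list their median was -1.24 (camera, adjusted p = 3.3e-31, and adjusted p = 0.232 with an estimated correlation), with Rps13 at -1.93 ± 0.28 (adjusted p = 6.35e-08, 12 of 12). All 8 of these embryos in C57BL/6 x JF1/Ms and all 4 in JF1/Ms x C57BL/6 had a mean ribosome biogenesis level below the 2PN median of their cross.

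Transcripts inherited from the oocyte were higher in the same embryos, with 44 of 58 higher and 1 lower, or 45 and 2 adjusted over the list alone. The members had a median of 1.06 (camera, adjusted p = 1.43e-13, and adjusted p = 0.232 with an estimated correlation). Btg4, an adaptor in the clearance of maternal mRNA on chromosome 9 at 51102147 to 51119924 (GRCm38), stood at 2.87 ± 0.27 (adjusted p = 3.48e-14, 12 of 12), Zbed3, a protein of the maternal subcortical complex, at 2.70 ± 0.27 (adjusted p = 4.17e-13, 12 of 12) and Cnot6l, a deadenylase, at 1.70 ± 0.21 (adjusted p = 4.71e-10, 12 of 12). Transcripts of the 2-cell stage had 3 of 44 higher and 12 lower, or 3 and 12 adjusted over the list alone. Over the list the median was -0.29 (camera, adjusted p = 2.36e-05, and adjusted p = 0.433 with an estimated correlation). Obox3 and Obox6, homeobox genes of a multicopy family and so uncertain, stood at -1.65 ± 0.33 (adjusted p = 2.47e-05, 12 of 12) and -1.85 ± 0.34 (adjusted p = 8.78e-06, 12 of 12). Without embryos 1 and 2 of JF1/Ms x C57BL/6, a choice made after seeing the data, 8 of these genes were lower, and camera no longer called the list (adjusted p = 0.225). Oocyte-derived genes then had 34 higher and 2 lower, and ribosome biogenesis genes 42 lower.

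Genes expressed from the paternal allele alone, which an embryo without a paternal genome should lack, had 8 of 35 higher and 15 lower, or 8 and 16 adjusted over the list alone. The median log2 fold change was -0.99 (camera, adjusted p = 0.00730, and adjusted p = 0.284 with an estimated correlation). Zrsr1, a splicing factor retrogene on chromosome 11 at 22972005 to 22976496 (GRCm38), fell by 5.67 ± 0.55 (adjusted p = 1.78e-14, 12 of 12) and Mcts2, a retrogene on chromosome 2 at 152687148 to 152687946 (GRCm38), fell by 3.89 ± 0.41 (adjusted p = 8.63e-13, 12 of 12). Etv6 fell by 3.74 ± 0.50 (adjusted p = 3.29e-09, 12 of 12) and Snhg14 by 2.84 ± 0.40 (adjusted p = 2.39e-08, 12 of 12). Zrsr1 and Mcts2 lie in introns of other genes and Snhg14 overlaps its neighbours, so reads may be shared between them. Genes expressed from the maternal allele had 8 of 24 higher and 2 lower, or 8 and 2 adjusted over the list alone. These genes had a median of 0.56 (camera, adjusted p = 0.357), with Meg3, a long non-coding RNA, at 2.06 ± 0.34 (adjusted p = 4.38e-07, 11 of 12) and Igf2r, the receptor that clears Igf2, at -1.58 ± 0.36 (adjusted p = 0.000198, 10 of 12). The Y-linked list had 0 of 8 higher and 7 lower, or 0 and 7 adjusted over the list alone (camera, adjusted p = 0.00523, and adjusted p = 0.410 with an estimated correlation). Eif2s3y and Usp9y had 0 counts in all 12 embryos and were at least 385.8-fold and at least 291.6-fold lower, against a floor of 3 counts over the group.

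Housekeeping machinery was lower in part. Splicing factors had 1 of 46 higher and 30 lower, or 1 and 30 adjusted over the list alone. Their median was -0.73 (camera, adjusted p = 5.54e-09, and adjusted p = 0.232 with an estimated correlation), with Hnrnpa1 at -1.18 ± 0.22 (adjusted p = 6.68e-06, 12 of 12). Proteasome subunits had 2 of 32 higher and 21 lower, or 2 and 25 adjusted over the list alone. The list median was -0.96 (camera, adjusted p = 5.65e-07, and adjusted p = 0.299 with an estimated correlation), with Psmd7 at -1.91 ± 0.29 (adjusted p = 1.31e-07, 12 of 12) and Psmb3 at 2.00 ± 0.29 (adjusted p = 6.63e-08, 12 of 12). Nuclear import and envelope genes had 7 of 63 higher and 29 lower, or 7 and 29 adjusted over the list alone. As a list their median was -0.50 (camera, adjusted p = 0.000212, and adjusted p = 0.232 with an estimated correlation), with the nucleoporin genes Nup155 at -1.63 ± 0.27 (adjusted p = 1.22e-06, 12 of 12) and Ranbp2 at -1.29 ± 0.21 (adjusted p = 4.01e-07, 12 of 12) and the oocyte histone chaperone gene Npm2 at 1.01 ± 0.18 (adjusted p = 2.95e-06, 12 of 12). Mitosis genes had 8 of 49 higher and 23 lower, or 9 and 25 adjusted over the list alone. The members had a median of -0.49 (camera, adjusted p = 0.000452, and adjusted p = 0.299 with an estimated correlation), with Top2a at -1.60 ± 0.24 (adjusted p = 5.61e-08, 12 of 12) and Aurka at -1.18 ± 0.22 (adjusted p = 7.02e-06, 12 of 12). DNA replication genes had 5 of 49 higher and 17 lower, or 7 and 18 adjusted over the list alone. Over the list the median was -0.41 (camera, adjusted p = 0.00579, and adjusted p = 0.324 with an estimated correlation). Nuclear genes of the respiratory chain had 7 of 62 higher and 21 lower, or 7 and 21 adjusted over the list alone. The median log2 fold change was -0.28 (camera, adjusted p = 0.00125, and adjusted p = 0.316 with an estimated correlation).

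The other lists did not pass camera in this comparison. Chromatin and DNA methylation genes had 8 of 48 higher and 15 lower, or 8 and 15 adjusted over the list alone (adjusted p = 0.272), p53 targets 6 of 38 higher and 8 lower, or 5 and 8 adjusted over the list alone (0.283), heat shock and stress genes 12 of 42 higher and 14 lower, or 12 and 14 adjusted over the list alone (0.143) and apoptosis genes 8 of 35 higher and 6 lower, or 8 and 6 adjusted over the list alone (0.909). Glycolysis genes had 8 of 30 higher and 5 lower, or 8 and 5 adjusted over the list alone (0.674), early lineage genes 9 of 27 higher and 9 lower, or 9 and 10 adjusted over the list alone (0.426) and mitochondrially encoded genes 1 of 13 higher and 0 lower, or 0 and 0 adjusted over the list alone (0.449). Markers of cumulus and granulosa cells had 3 of 11 higher and 2 lower, or 3 and 2 adjusted over the list alone (0.718), of sperm and testis 6 of 17 higher and 3 lower, or 6 and 3 adjusted over the list alone (0.916) and of blood, immune and other cells 2 of 11 higher and 2 lower, or 2 and 2 adjusted over the list alone (0.837). Among single genes Flrt2, a cell adhesion receptor, fell by 6.84 ± 1.16 (adjusted p = 1.71e-06, 12 of 12), and Cr1l, a complement regulator, rose by 2.98 ± 0.35 (adjusted p = 3.3e-12, 12 of 12) and Smco4 by 2.99 ± 0.38 (adjusted p = 1.24e-10, 12 of 12). In all 6053 of 22785 genes were higher and 4160 lower. The balance differed between crosses, with 4500 higher and 3213 lower in C57BL/6 x JF1/Ms and 3582 and 4900 in JF1/Ms x C57BL/6. A stricter filter on low counts left 6496 and limma voom called 6437, and simulated data showed that the edgeR test calls too many genes of low count.

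**Figure D3:**
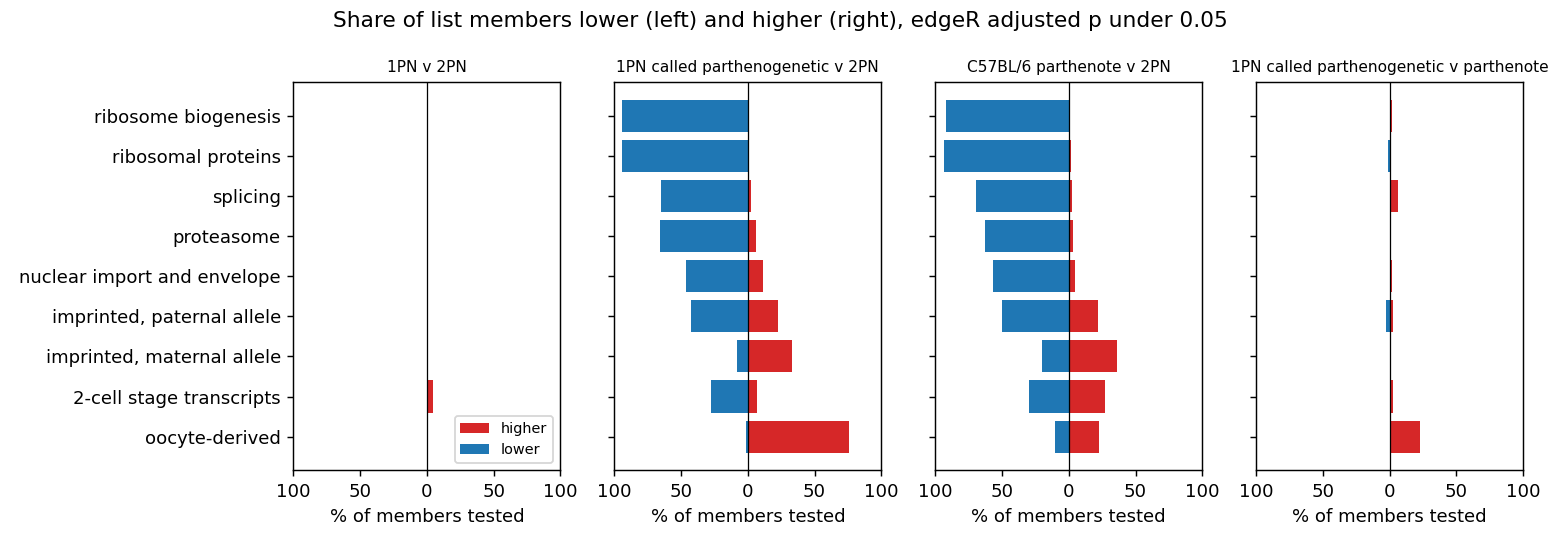
Share of the tested members of 9 gene lists that were lower (blue, left) or higher (red, right) at an edgeR adjusted p under 0.05 (x axis, percent), in 4 comparisons. Ribosome biogenesis genes were lower in 48 of 51 cases in 1PN embryos called parthenogenetic against 2PN, in 47 of 51 in parthenotes against 2PN and in 0 in 1PN against 2PN.

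Whether this difference was the same in both crosses was tested next, because an embryo without a paternal genome carries only 1 of the strains. Ribosome biogenesis genes were lower by more in JF1/Ms x C57BL/6 than in C57BL/6 x JF1/Ms, with 0 of 51 higher and 26 lower, or 0 and 34 adjusted over the list alone. These genes had a median of -1.51 (camera, adjusted p = 3.41e-11, and adjusted p = 0.407 with an estimated correlation). Ribosomal protein genes were also lower by more, with 1 of 74 higher and 35 lower, or 1 and 48 adjusted over the list alone. Their median was -1.28 (camera, adjusted p = 4.09e-15, and adjusted p = 0.407 with an estimated correlation). Oocyte-derived genes had a more positive difference, with 10 of 58 higher and 1 lower, or 11 and 1 adjusted over the list alone. The list median was 0.42 (camera, adjusted p = 7.59e-07, and adjusted p = 0.407 with an estimated correlation). The median over all genes was -0.68, against which these medians are to be read. Txndc8 stood at -8.73 ± 0.92 (adjusted p = 4.28e-13) in C57BL/6 x JF1/Ms and 2.77 ± 0.83 (adjusted p = 0.00551) in JF1/Ms x C57BL/6, a difference of 11.50 ± 1.48 (adjusted p = 3.09e-09), and Npy, the neuropeptide Y precursor, at -9.72 ± 1.38 (adjusted p = 1.66e-08) and 3.99 ± 0.62 (adjusted p = 1.4e-07), a difference of 13.71 ± 1.48 (adjusted p = 1.92e-12). In all 998 of 24380 genes had a more positive and 2876 a more negative difference in JF1/Ms x C57BL/6. With upper-quartile factors these were 2145 and 1901. Without embryo 1 or embryo 2 of JF1/Ms x C57BL/6 1784 and 2066 genes passed, and without both 570. Without both, 4 ribosome biogenesis and 3 ribosomal protein genes had a more negative difference, and the oocyte-derived list had 0 members past the threshold with edgeR and a median of -0.37.

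1PN embryos called parthenogenetic were also set against the other 1PN embryos, which were scored alike under the microscope. Ribosome biogenesis genes had 0 of 51 higher and 47 lower, or 0 and 48 adjusted over the list alone. As a list their median was -1.22 (camera, adjusted p = 2.16e-24, and adjusted p = 0.207 with an estimated correlation). Oocyte-derived genes had 42 of 58 higher and 1 lower, or 45 and 2 adjusted over the list alone. The members had a median of 1.32 (camera, adjusted p = 1.68e-14, and adjusted p = 0.207 with an estimated correlation). Tsr1 fell by 3.30 ± 0.33 (adjusted p = 7.66e-13, 12 of 12) and Zrsr1 fell by 5.89 ± 0.58 (adjusted p = 2.5e-13, 12 of 12), and Btg4 rose by 3.10 ± 0.42 (adjusted p = 4.88e-08, 12 of 12). Adh7, an alcohol dehydrogenase gene, and Usp9y had 0 counts and were at least 120.7-fold and at least 468.4-fold lower. In all 4700 of 22785 genes were higher and 3526 lower, and limma voom called 5354. Within C57BL/6 x JF1/Ms 4119 genes passed.

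C57BL/6 parthenotes, compared with 2PN embryos of C57BL/6 x JF1/Ms, likewise had fewer ribosome transcripts. Ribosome biogenesis genes had 0 of 51 higher and 47 lower, or 0 and 48 adjusted over the list alone. Over the list the median was -0.85 (camera, adjusted p = 3.19e-17, and adjusted p = 0.163 with an estimated correlation). The mean level lay below the 2PN median in 31 of 31 parthenotes. Tsr1 stood at -2.53 ± 0.18 (adjusted p = 9.25e-25, 31 of 31) and Npm1, which encodes nucleophosmin, at -1.11 ± 0.12 (adjusted p = 5.74e-14, 31 of 31). Ribosomal protein genes had 1 of 74 higher and 69 lower, or 1 and 69 adjusted over the list alone. The median log2 fold change was -0.90 (camera, adjusted p = 2.62e-22, and adjusted p = 0.163 with an estimated correlation). Oocyte-derived genes, in contrast, had 13 of 58 higher and 6 lower, or 13 and 6 adjusted over the list alone. These genes had a median of 0.10 (camera, adjusted p = 0.221). Nuclear import and envelope genes had 3 of 63 higher and 36 lower, or 3 and 36 adjusted over the list alone. Their median was -0.58 (camera, adjusted p = 6.47e-07, and adjusted p = 0.0903 with an estimated correlation), with the GTPase gene Ran at -1.09 ± 0.14 (adjusted p = 2e-11, 31 of 31). Chromatin and DNA methylation genes had 7 of 48 higher and 24 lower, or 8 and 24 adjusted over the list alone. The list median was -0.28 (camera, adjusted p = 0.00130, and adjusted p = 0.0903 with an estimated correlation), with Ctcf, which encodes an insulator protein, at -1.13 ± 0.11 (adjusted p = 1.04e-15, 31 of 31) and Chaf1a, a histone chaperone subunit gene, at -1.50 ± 0.16 (adjusted p = 1.22e-14, 31 of 31).

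In parthenotes paternally expressed imprinted genes had 8 of 36 higher and 18 lower, or 8 and 18 adjusted over the list alone. As a list their median was -0.95 (camera, adjusted p = 4.78e-05, and adjusted p = 0.0903 with an estimated correlation). Snrpn, a spliceosomal protein gene of the Prader-Willi region, stood at -2.61 ± 0.18 (adjusted p = 2.79e-25, 31 of 31), Mcts2 at -3.44 ± 0.25 (adjusted p = 7.42e-24, 31 of 31) and Zrsr1 at -3.86 ± 0.30 (adjusted p = 2.52e-23, 31 of 31). Slco6d1 had 0 counts in 31 parthenotes and was at least 1201-fold lower. Of the early lineage genes, Sox2 stood at 3.38 ± 0.35 (adjusted p = 1.04e-16, 28 of 31), Eomes at 3.33 ± 0.36 (adjusted p = 2.35e-15, 27 of 31) and Sox17 at 5.36 ± 0.69 (adjusted p = 9.33e-11, 19 of 31), while the list they belong to did not pass (10 of 27 higher and 5 lower, or 10 and 6 adjusted over the list alone; camera, adjusted p = 0.851). Perp, a p53 target, stood at 5.34 ± 0.40 (adjusted p = 3.16e-26, 30 of 31) and Irx2 at 4.43 ± 0.35 (adjusted p = 6.13e-23, 30 of 31). Markers of cumulus and granulosa cells, which surround the oocyte, had 10 of 18 higher and 0 lower, or 10 and 0 adjusted over the list alone. The members had a median of 1.56 (camera, adjusted p = 0.0323, and adjusted p = 0.255 with an estimated correlation), with Tnfaip6 at 2.18 ± 0.29 (adjusted p = 6.05e-11, 29 of 31). Markers of blood, immune and other cells had 8 of 13 higher and 1 lower, or 8 and 1 adjusted over the list alone. Over the list the median was 0.96 (camera, adjusted p = 0.0300, and adjusted p = 0.202 with an estimated correlation), with the globin gene Hba-a2, whose copies share reads, at 2.52 ± 0.28 (adjusted p = 1.54e-14, 31 of 31).

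In all 7106 of 24380 genes were higher in parthenotes and 5306 lower. The balance of higher and lower calls rested on the scaling, with 8915 higher and 4210 lower with RLE factors, and 9259 and 3953 with library totals alone. The median of all genes moved from 0.18 to 0.38 and 0.41. A stricter filter left 7376 genes. Parthenotes lack both the paternal genome and the JF1/Ms alleles of the hybrids, so strain and paternal genome cannot be separated in this comparison.

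1PN embryos called parthenogenetic of C57BL/6 x JF1/Ms and C57BL/6 parthenotes, both without a paternal genome by their labels, differed most clearly in oocyte-derived transcripts, which had 13 of 58 higher and 0 lower, or 24 and 0 adjusted over the list alone. The median log2 fold change was 0.68 (camera, adjusted p = 1.11e-11, and adjusted p = 0.383 with an estimated correlation). Ooep, a gene of the maternal subcortical complex, stood at 1.51 ± 0.27 (adjusted p = 0.000133, 8 of 8), Zbed3 at 1.72 ± 0.32 (adjusted p = 0.000185, 8 of 8) and H1foo, the oocyte linker histone gene, at 1.37 ± 0.31 (adjusted p = 0.00274, 7 of 8). Zfp57, a zinc finger gene needed to keep imprints, stood at 1.78 ± 0.25 (adjusted p = 3.53e-07, 7 of 8). Perp fell by 3.26 ± 0.61 (adjusted p = 0.000172, 8 of 8) and the keratin gene Krt18 fell by 5.82 ± 1.26 (adjusted p = 0.00146, 8 of 8). Markers of blood, immune and other cells had 0 of 13 higher and 2 lower, or 0 and 2 adjusted over the list alone. These genes had a median of -0.85 (camera, adjusted p = 0.0109, and adjusted p = 0.383 with an estimated correlation). Ribosomal protein genes had 0 of 74 higher and 1 lower, or 0 and 1 adjusted over the list alone. Their median was -0.09 (camera, adjusted p = 0.0457, and adjusted p = 0.989 with an estimated correlation), and over the alternatives the median ran from -0.14 to 0.06. In all 831 of 24380 genes were higher and 383 lower. Without embryo 10 or embryo 4 of the 1PN group called parthenogenetic 418 and 762 passed, while DESeq2 called 450 and limma voom 405.

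The changes of these embryos and of parthenotes were compared across 19198 genes, each against its own part of the 2PN embryos split by odd and even number. Pearson's r was 0.733, Spearman's rho 0.707 and the covariance 1.31, and 0.681, 0.631 and 1.26 with the parts exchanged. Genes are not independent replicates. With all 2PN embryos in both, r was 0.778 and the covariance 1.32, where 10 simulations of unchanged groups gave means of 0.243 and 0.0555. Against all 2PN embryos of the cross, 2872 genes were higher in both, of 4500 and 7106, where independent lists would share 1312. A further 2789 were lower in both, of 3213 and 5306, where independent lists would share 699, and 34 went in opposite directions. The simulated values leave out real effects and the independent lists leave out the shared controls. If the first strain named is the mother, both groups also lack the alleles of the paternal strain of the hybrids. Differences of strain or of mapping to the reference could then move both groups alike. This agreement therefore cannot separate them from the absence of a paternal genome.

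Reciprocal 2PN hybrids have the same autosomal genotype with the strains of the parents exchanged. Mitochondrially encoded genes differed in every tested case in JF1/Ms x C57BL/6, with 4 of 13 higher and 9 lower, or 4 and 9 adjusted over the list alone. The list median was -0.62 (camera, adjusted p = 0.0318, and adjusted p = 0.745 with an estimated correlation). Of these mt-Nd4l fell by 4.85 ± 0.19 (adjusted p = 1.54e-48, 21 of 21) while mt-Co2 rose by 3.43 ± 0.15 (adjusted p = 1.23e-42, 21 of 21). Prox1, a homeobox gene on chromosome 1 at 190118035 to 190170827 (GRCm38), stood at 8.78 ± 0.45 (adjusted p = 6.7e-27, 21 of 21) and Bfsp1, a lens filament gene on chromosome 2 at 143826528 to 143915219 (GRCm38), at 9.45 ± 0.65 (adjusted p = 2.86e-16, 21 of 21). The imprinted genes Snrpn and Kcnq1ot1, an antisense RNA, stood at 2.19 ± 0.17 (adjusted p = 3.07e-22, 20 of 21) and 2.34 ± 0.30 (adjusted p = 2.56e-11, 18 of 21), while their list did not pass (12 of 36 higher and 6 lower, or 14 and 7 adjusted over the list alone; camera, adjusted p = 0.234). Transcripts of the 2-cell stage had 19 of 44 higher and 1 lower, or 20 and 1 adjusted over the list alone. As a list their median was 0.56 (camera, adjusted p = 0.0318, and adjusted p = 0.745 with an estimated correlation). Oocyte-derived genes had 12 of 58 higher and 20 lower, or 13 and 20 adjusted over the list alone. The members had a median of -0.23 (camera, adjusted p = 0.0127, and adjusted p = 0.745 with an estimated correlation). Proteasome genes had 0 of 32 higher and 15 lower, or 0 and 16 adjusted over the list alone. Over the list the median was -0.51 (camera, adjusted p = 3.05e-05, and adjusted p = 0.745 with an estimated correlation). Ribosome biogenesis genes had 2 of 51 higher and 15 lower, or 2 and 14 adjusted over the list alone. The median log2 fold change was -0.23 (camera, adjusted p = 0.000549, and adjusted p = 0.745 with an estimated correlation). Nuclear import and envelope genes had 9 of 63 higher and 17 lower, or 9 and 17 adjusted over the list alone. These genes had a median of -0.14 (camera, adjusted p = 0.0318, and adjusted p = 0.745 with an estimated correlation), and was above 0 with upper-quartile factors. In all 4592 of 24380 genes were higher and 4670 lower, or 5499 and 3696 with upper-quartile factors. Reads of JF1/Ms alleles were aligned to a C57BL/6 reference, and the libraries of JF1/Ms x C57BL/6 were shallower. Whether either gave rise to these differences, those of mitochondrially encoded genes included, was not tested. The values of these genes therefore need not be differences of expression.

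Measures of the libraries differed between some groups. Mitochondrially encoded transcripts took 7.13% ± 2.24 (SD, n = 31) of counts in parthenotes, 7.40% ± 3.06 (SD, n = 8) in 1PN embryos called parthenogenetic of C57BL/6 x JF1/Ms and 5.31% ± 1.10 (SD, n = 43) in 2PN embryos of that cross (permutation tests against 2PN, 2-sided, adjusted p = 0.000103 and adjusted p = 0.0156). Cumulus and granulosa markers summed to 92.4 CPM ± 49.6 (SD, n = 31), 72.0 CPM ± 28.6 (SD, n = 8) and 21.9 CPM ± 15.02 (SD, n = 43) in the same order (permutation tests, adjusted p = 0.000103 for both, from the smallest p that 100000 resamples can give). Blood, immune and other markers summed to 598 CPM ± 164 (SD, n = 31) in parthenotes and 440 CPM ± 142 (SD, n = 43) in 2PN embryos (permutation test, adjusted p = 0.0004). 1PN embryos called parthenogenetic of JF1/Ms x C57BL/6 had a mitochondrial share of 3.17% ± 2.23 (SD, n = 4) against 3.17% ± 1.88 (SD, n = 21) in 2PN embryos (exact permutation test, adjusted p = 0.999). Their cumulus and granulosa markers summed to 22.2 CPM ± 15.8 (SD, n = 4) against 18.4 CPM ± 19.9 (SD, n = 21) (exact permutation test, adjusted p = 0.802). With counts thinned to a common depth, which left 3 of these embryos and 16 2PN embryos, the 50 most counted genes took 21.6 ± 1.38% against 15.3 ± 2.17% of counts (mean ± SD; exact permutation test, adjusted p = 0.013). Sperm and testis markers then summed to 157 ± 44.8 CPM against 76.1 ± 28.9 CPM (exact permutation test, adjusted p = 0.0163). As deposited neither passed (adjusted p = 0.109 for each). None of the 8 measures differed between 1PN and 2PN embryos in either cross, with the cumulus and granulosa markers of C57BL/6 x JF1/Ms 1PN embryos at 25.6 CPM ± 14.9 (SD, n = 11) (permutation test, adjusted p = 0.642).

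1PN embryos called parthenogenetic lay further from the rest of their group than 2PN embryos did, but their groups were smaller. The mean of 1 minus Spearman's rho between an embryo and the rest of its group was 0.138 ± 0.0321 (SD, n = 8) in 1PN embryos called parthenogenetic and 0.0950 ± 0.0232 (SD, n = 43) in 2PN embryos of C57BL/6 x JF1/Ms (permutation test, 2-sided, adjusted p = 0.00184). In JF1/Ms x C57BL/6 it was 0.253 ± 0.0179 (SD, n = 4) and 0.152 ± 0.0546 (SD, n = 21) (exact permutation test, adjusted p = 0.00902), a difference that was lost over the 2000 genes with the highest mean CPM. In 1PN embryos it was 0.104 ± 0.0390 (SD, n = 11) (permutation test, adjusted p = 0.357) in the first cross, and the exact permutation test gave adjusted p = 0.504 in the reciprocal cross. Against 1PN embryos the spread of those called parthenogenetic did not pass (exact permutation tests, adjusted p = 0.0898 in C57BL/6 x JF1/Ms and adjusted p = 0.0514 in JF1/Ms x C57BL/6). The rest of a group is 3 or 7 embryos here and 20 or 42 for 2PN embryos, and a mean of few embryos is noisier. The permutations moved the values without computing them anew, so the p-values do not allow for group size. Whether embryos called parthenogenetic were less alike than 2PN embryos therefore cannot be told. In parthenotes the mean of 1 minus rho was 0.104 ± 0.0244 (SD, n = 31) (permutation test, adjusted p = 0.166).

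**Figure D4:**
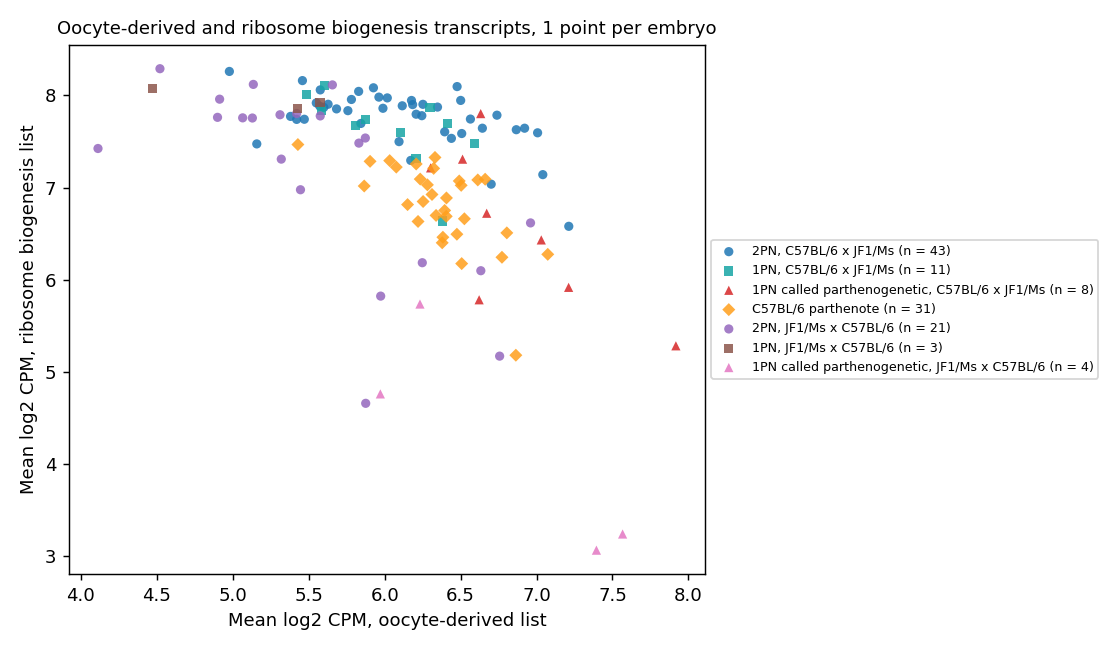
Mean log2 CPM of the oocyte-derived list (x axis) against that of the ribosome biogenesis list (y axis), with 1 point per embryo and groups shown by colour and shape. On the y axis parthenotes had a mean of 6.81 ± 0.46 (SD, n = 31) and 2PN embryos of C57BL/6 x JF1/Ms of 7.76 ± 0.31 (SD, n = 43).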

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

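All tests of explanations in this part, including the splits of the embryos, were written down only after the results they bear on had been seen. Library measures, spread and list scores of 1PN embryos called parthenogenetic, in each cross, were searched for an embryo far from the others. No other group was searched. Chance marks about 1 in 20 such sets of values if they are independent, which these are not. Of 66 sets tested 2 were marked where 3.3 would be expected. These were the Xist counts of 1PN embryos called parthenogenetic, where embryo 19 of C57BL/6 x JF1/Ms had 160 and embryo 2 of JF1/Ms x C57BL/6 had 2, the highest of their groups.

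The difference between 1PN embryos called parthenogenetic and 2PN embryos itself differed between crosses in 3874 genes, or 1784 without embryo 1 of JF1/Ms x C57BL/6, 2066 without embryo 2 and 570 without both. The log2 fold change was more negative in JF1/Ms x C57BL/6 for Rps23 at -3.53 ± 0.56, Rpl6 at -3.81 ± 0.63, Nop16 at -4.86 ± 0.80, Nhp2 at -2.80 ± 0.56 (log2, SE). It was also more negative for Nat8f2 at -7.16 ± 0.90, Spz1 at -10.06 ± 1.29, Uqcrfs1 at -5.34 ± 0.76, Psma2 at -3.70 ± 0.53 and Xist at -6.81 ± 1.65 (log2, SE). It was more positive for Nanog at 3.23 ± 0.82, Tdrd12 at 2.30 ± 0.53, Npy at 13.71 ± 1.48, Txndc8 at 11.50 ± 1.48 and Serpinb3b at 10.86 ± 1.49. Against a median of -0.68 over all genes, the lists called by camera had median differences of -0.69 for 2-cell stage transcripts, -1.51 for ribosome biogenesis, -1.28 for ribosomal proteins and -1.17 for DNA replication. They were -1.47 for proteasome, -1.01 for splicing, 0.42 for oocyte-derived genes and 0.33 for paternally expressed imprinted genes, whose mean was -0.22. None passed with an estimated correlation, where the adjusted p was 0.792 for proteasome and 0.407 for each other list.

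Of the libraries kept out of all comparisons, the embryo labelled dead had 19.2% of counts in mitochondrially encoded genes and 39.2% in its 50 most counted genes. Embryo 8 of those labelled of low quality had 10.98% and 88.7 CPM of cumulus and granulosa markers. The highest mitochondrial share of a 2PN embryo of the same cross was 7.74%, and the highest share of the top 50 genes 26.5%. Some kept embryos without a paternal genome by their labels exceeded embryo 8. Parthenote 27 had a mitochondrial share of 14.1% and embryo 4 of the C57BL/6 x JF1/Ms 1PN group called parthenogenetic 13.8%. Parthenote 11 had 274 CPM of cumulus and granulosa markers. No kept embryo reached the shares of the embryo labelled dead.

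The genes higher in 1PN than in 2PN embryos may rest on 1 embryo, since without embryo 9 of C57BL/6 x JF1/Ms 1 gene, Irx2, passed in place of 23. Library size alone is argued against, because with counts thinned to a common depth, which left out 6 libraries, 40 genes passed and 20 of them were among the 23. Of 40 splits of the same embryos into groups of the same sizes, the real one included, 18 gave at least the real 16 genes. The highest was 170, so chance cannot be excluded. Within C57BL/6 x JF1/Ms 10 of 40 splits gave as many as the real 14, with a highest of 116. In JF1/Ms x C57BL/6 and for the difference between crosses the real count was 0, which 40 of 40 splits reach. The highest others were 2515 and 1374. Such counts point to a structure of the samples, which may be no more than outlying libraries in small groups or false calls of the test. Simulated data gave 19 false calls of 58 for 1PN against 2PN in JF1/Ms x C57BL/6. Whether any of these gave rise to the counts of the splits was not tested.

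Fewer ribosome transcripts in embryos called parthenogenetic were seen in 118 of 125 members of both ribosome lists. Library size as the whole cause is argued against by 118 lower after thinning. The 2 embryos nearest the dead one are argued against by 110 lower without embryos 1 and 2 of JF1/Ms x C57BL/6. Embryos less far out on the first principal component stayed in (155.93 for embryo 7 of that cross, 148.27 for embryo 10 of C57BL/6 x JF1/Ms). On the other side 2PN embryo 8 of JF1/Ms x C57BL/6, at 161.73, stayed in too. A strain or mapping difference would take opposite signs in the crosses, and 117 members were lower in JF1/Ms x C57BL/6 and 99 in C57BL/6 x JF1/Ms. In parthenotes the ribosome biogenesis level was -0.95 against 2PN embryos. It was -0.86 after the trend of 2PN embryos with the oocyte-derived level was removed (SD of 2PN residuals 0.256, permutation test, adjusted p = 1.5e-05). The oocyte-derived level was 6.36 ± 0.32 (SD) in parthenotes and 6.10 ± 0.54 (SD) in 2PN embryos, so the trend could remove little. Slower loss of maternal transcripts as the whole cause is argued against in parthenotes only if that trend holds for them, which was not tested. The absence of a paternal genome and a slower or arrested development stay open as untested explanations. The way parthenotes were made stays open for parthenotes alone. The 118 lower members are those of 1PN embryos called parthenogenetic, which came from the crosses.

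Of the genes lower in C57BL/6 parthenotes than in 2PN embryos by at least 4 on the log2 scale, 96 were protein-coding. If absence of the paternal genome alone were the cause, they would also be lower in 1PN embryos called parthenogenetic of JF1/Ms x C57BL/6, where their median was -0.52 (quartiles -3.68 and 0.55) with 11 lower. This argues against it as the whole cause, although 31 of the 96 were already lower in 2PN embryos of that cross than of the reciprocal one (median -0.71), and the 85 lower in C57BL/6 x JF1/Ms were compared with the 2PN embryos that the genes were chosen on. JF1/Ms alleles or their mapping to the reference cannot be told apart from other causes, since only 7 of these genes were higher in embryos with only the JF1/Ms genome and that group has 4 embryos. Both readings assume that the first strain named is the mother.

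For the other comparisons 1 of 40 splits, the real grouping itself, gave as many genes, a share under 0.05. Chance placement of single embryos can be excluded at that level except for the difference between crosses. There the splits mixed 1PN embryos called parthenogenetic with 2PN embryos within each cross. Such splits stand for no effect in either cross, not for an equal effect in both, and so cannot decide it. The real count and the highest other were 9844 and 689 for 1PN embryos called parthenogenetic against 2PN, 6455 and 713 against 1PN, 3564 and 2283 for their difference between crosses. They were 9259 and 102 for parthenotes against 2PN, 1554 and 294 for 1PN embryos called parthenogenetic against parthenotes, and 6820 and 358 for reciprocal 2PN embryos. These fits held only the groups compared, so real counts differ from those of the comparisons. All splits treated embryos as exchangeable, and no label used here says which embryos share parents or a day. A difference of parents or day between groups is therefore not excluded.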

How the results depend on the processing

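Every alternative was planned except each cross alone, protein-coding genes only, C57BL/6 x JF1/Ms embryos left out in turn, lists without doubted embryos, and embryos 1 and 2 of the JF1/Ms x C57BL/6 1PN group called parthenogenetic left out, which were chosen after seeing the data. Under alternatives there were 3191 values for 163 pairs of a named gene and a comparison, where a gene can count in several comparisons. Of these values 3079 kept direction and side of the threshold, 102 lost the threshold and 10 changed direction. The rule for named genes favours those past the threshold. Counts for 1PN embryos called parthenogenetic and for parthenotes against 2PN stayed within 1.5 times under all scalings and with DESeq2, while counts for 1PN against 2PN moved under most alternatives. Depth limits genes of low count most, where simulated data gave many false edgeR calls. From RLE factors to library totals the median of all genes went from 0.38 to 0.41 for parthenotes against 2PN, with 0.12 under upper-quartile factors. Where no cause is given below, the cause was not tested.

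For 1PN against 2PN in both crosses, in C57BL/6 x JF1/Ms and in JF1/Ms x C57BL/6, the counts of genes were 8, 24 and 663 with DESeq2. In the same order they were 1, 0 and 95 with limma voom, 61, 148 and 9 with the older quasi-likelihood test. They were 111, 155 and 139 without a filter, 4, 15 and 0 with a stricter filter. They were 3, 8 and 0 over protein-coding genes only, where fewer genes were tested. With only the groups compared they were 14 in C57BL/6 x JF1/Ms and 0 in JF1/Ms x C57BL/6. With counts thinned they were 40 in both crosses and 0 in JF1/Ms x C57BL/6. RLE factors and library totals alone gave 1 and 1 in JF1/Ms x C57BL/6. Each cross alone, taken as the within-cross contrast of the fit of all 7 groups and so no separate fit, repeated the 48 and 2 above. Grouping embryos as scored under the microscope gave 3057, and putting low-quality and dead libraries back gave 460. The first of these adds the embryos called parthenogenetic to the 1PN group. The difference of the 1PN effect between crosses gave 484 with DESeq2, 47 with limma voom, 5 with the older test and 186 without a filter.

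The counts for 1PN embryos called parthenogenetic against 2PN were 6437 with limma voom and 6496 with a stricter filter. Against 1PN they were 5354 with limma voom and 4119 in C57BL/6 x JF1/Ms only. The difference between crosses gave 570 without embryos 1 and 2 of JF1/Ms x C57BL/6. Against parthenotes the counts were 450 with DESeq2, 405 with limma voom, 459 with the older test, 1922 without a filter and 770 with a stricter filter. A stricter filter, which tests fewer genes, gave 7376 for parthenotes against 2PN and 6014 for reciprocal 2PN embryos.

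Embryo numbers share only a number, because the labels tie them to no shared animal or day and not every embryo correlated best with its own number, as 0 of 11 did for 1PN against 2PN in C57BL/6 x JF1/Ms (median correlation -0.0787). With the number as a block, on embryos whose number both groups share, counts were 0, 0 and 0 for 1PN against 2PN in both crosses and in each. They were 2520 for 1PN embryos called parthenogenetic against 2PN, 6 against parthenotes, 8320 for parthenotes against 2PN and 4295 for reciprocal 2PN embryos.

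With embryos left out in turn, counts ranged from 1 to 35 for 1PN against 2PN in both crosses (the highest without embryo 5 of JF1/Ms x C57BL/6). They ranged from 0 to 54 in C57BL/6 x JF1/Ms and 1 to 2 in JF1/Ms x C57BL/6. For the difference of the 1PN effect they were 0 each time, but only the 3 JF1/Ms x C57BL/6 1PN embryos were left out there. Counts also ranged from 9169 to 10586 for 1PN embryos called parthenogenetic against 2PN. Against 1PN the range was 7504 to 8340, where only the 7 embryos of JF1/Ms x C57BL/6 were left out in turn. The ranges were 1784 to 4796 for the difference between crosses and 418 to 1555 against parthenotes. Without embryo 9 of the C57BL/6 x JF1/Ms 1PN group 4 lists passed camera for 1PN against 2PN. Usp17la, Pramef6 and Hip1 then stood at -0.37, -0.28 and -0.33 in both crosses, where leaving out other embryos gave up to 2.55, 2.04 and 2.13. Zscan4b and Pramef6 stood at -0.30 and -0.25 in C57BL/6 x JF1/Ms, against up to 2.54 and 2.39 without others. In JF1/Ms x C57BL/6 only, the reversed values were -2.89 for Usp17la, -0.41 for Pramef6 and -0.62 for Hip1 in 1PN embryos. They were -2.16 for Celf4 and -1.93 for Wfdc2 in 1PN embryos called parthenogenetic.

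With an estimated correlation camera called 0 lists in each comparison. On ranks it called 5 for 1PN embryos called parthenogenetic against parthenotes. Directional fry called 0 lists for 1PN against 2PN and 14 for reciprocal 2PN embryos. Mixed fry called 0 for 1PN against 2PN, 0 against parthenotes, 17 for reciprocal 2PN embryos and 20 for parthenotes against 2PN. At a minimum of 1 count the difference in embryos with Y-linked counts was 0. Over the 2000 genes with the highest mean CPM the difference in spread was -0.00458 for parthenotes against 2PN and 0.00988 for 1PN embryos called parthenogenetic in JF1/Ms x C57BL/6. With counts thinned, which left out shallow libraries, 1PN minus 2PN in JF1/Ms x C57BL/6 was 0.000794 for spread and -244 for genes with counts. For 1PN embryos called parthenogenetic, genes with counts differed from 2PN by 1153 in C57BL/6 x JF1/Ms. In JF1/Ms x C57BL/6 the share of the top 50 genes differed by 6.30 percentage points and sperm and testis markers by 81.0 CPM. Blood, immune and other markers differed from 1PN by 12.7 CPM in C57BL/6 x JF1/Ms. Reciprocal 2PN embryos differed by -0.283 percentage points in the share of the top 50 genes and -10.1 CPM in cumulus and granulosa markers.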

Other observations

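Genes of the X chromosome were higher on balance in 1PN embryos called parthenogenetic of C57BL/6 x JF1/Ms and in parthenotes. In parthenotes against 2PN embryos their median log2 fold change was 0.45, with 343 of 883 higher and 140 lower, against a median of 0.17 for autosomal genes. In 1PN embryos called parthenogenetic of C57BL/6 x JF1/Ms it was 0.49 against 0.17, and in those of JF1/Ms x C57BL/6 -0.66 against -0.59. The 2PN embryos of C57BL/6 x JF1/Ms included males, with at least 50 Y-linked counts in 23 of 43 against 0 of 31 parthenotes. The sex of the embryos can therefore enter these medians. They were computed after seeing the data and the differences between chromosomes were not tested.

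In 1PN embryos called parthenogenetic 29.2% of 1835 pseudogenes and 19.2% of 15562 protein-coding genes were lower than in 2PN embryos, and the difference between these shares was not tested. Among reciprocal 2PN embryos Hk2, which encodes a hexokinase, stood at 5.28 ± 0.33 (adjusted p = 8.76e-34, 21 of 21) in JF1/Ms x C57BL/6. In C57BL/6 parthenotes Mycn stood at 4.32 ± 0.38 (adjusted p = 6.33e-21, 31 of 31) and Sp110, which encodes a nuclear body protein, at -2.03 ± 0.17 (adjusted p = 1.42e-20, 31 of 31).

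Of the libraries labelled of low quality, the 2PN library 20 of JF1/Ms x C57BL/6 had 4680 counts in 2555 genes, and embryo 6 of the C57BL/6 x JF1/Ms 1PN embryos had 3.87% of counts in mitochondrially encoded genes.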
